A study of Mus musculus with 12 samples.

How the data were processed

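RNA was measured in 12 libraries of lung CD4+ T cells, each from a separate pool of mice per the labels. Cells were enriched with magnetic beads and then sorted by flow cytometry 48 h after aspiration, and the gate beyond CD4 is not given in the sources used here. Per the labels, cDNA was made with an amplification kit that does not mark strand, and libraries were PCR-amplified and sequenced as 100 base pair paired ends on an Illumina HiSeq. Per the labels, the authors called bases with CASAVA 1.8.4 and aligned reads with STAR to GRCm38 (mm10). The deposited values are counts per gene symbol, in whole numbers and not normalized, made with SeqMonk as the deposited table is named. Its version, strand setting, gene annotation and any filter are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies such as Hspa1a and Hspa1b or ribosomal protein genes may be split between them. Counts were checked for duplicated libraries, and no 2 libraries of a group were alike beyond counting error (chi-square over degrees of freedom 3.88 to 19.6). The DNA methylation data of the series were not analysed here.

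All 12 columns were mapped to the groups of the labels. Replicates are the 3 pools of each group. Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 11062 of 19434 genes and 99.9% of the counts. The main test was edgeR 4.0.16 (R 4.3.3) quasi-likelihood F on group means of all 12 libraries with TMM scaling and no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Its common biological coefficient of variation was 0.123. The 5 contrasts were E. coli against PBS in neonates and in juveniles, the difference of these responses, and neonates against juveniles after PBS and after E. coli. Adjusted p-values of genes in the text are from edgeR unless another tool is named. CPM are counts scaled to the total over the tested genes of each library with its TMM factor, as mean ± SD of 3 libraries, and log2 fold changes are ± SE. Depth set a floor of 3 counts per library, 0.374 to 0.494 CPM. Against a group at 0 counts the fold is a bound at that floor, and with 1 to 3 counts in a group the ratio of counts is given with a 95% exact binomial interval. Tables and figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

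Gene lists, tests, contrasts, thresholds and the rule for naming genes were fixed before the data were examined. The rule names, per contrast, the 8 largest positive and 8 largest negative changes among called genes of average log2 CPM of at least 3 whose groups did not overlap (no such demand for the difference of responses), leaving out predicted genes and antigen receptor segments. Some genes the rule selects are not reported. It adds up to 4 members of smallest p from each list described, and a fixed set of T cell and DNA methylation genes. Coordinates are GRCm38, from GENCODE M21, where 17841 of the symbols were found. The 36 lists held 854 members as written, of which 827 matched the counted symbols, 8 through an older symbol. The mitochondrially encoded list was not tested, because its 13 members in the count table had 0 counts in every library, and whether reads of these genes were counted is not given in the sources used here. The other 35 lists were T cell identity, T cell activation, naive T cell and lymph node homing, Th1, Th2, Th17, regulatory T cell, follicular helper T cell, cytotoxic effector and CD8 T cell, immature T cell and recent thymic emigrant, cell cycle, interferon response, NF-kB target, STAT target and cytokine feedback, immediate early and dissociation stress, DNA methylation machinery, polycomb and chromatin regulator, fetal and neonatal program, lung homing and tissue residency, glycolysis and hypoxia, oxidative phosphorylation, ribosomal protein, B cell, neutrophil, monocyte and macrophage, dendritic cell and MHC class II, NK cell and innate lymphoid cell, gamma-delta and NKT cell, erythroid, lung epithelial, endothelial, fibroblast and smooth muscle, mast cell, basophil and eosinophil, platelet and megakaryocyte, and sex linked. They were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), adjusted over the 35 lists of a contrast, and again with a correlation estimated from the residuals and with fry. A list's members were also adjusted over the list alone, a second count that follows the first in the text. No list called by camera had a median or mean opposite in sign to its test. Among lists not called, the median was opposite in 4, 0, 4, 3 and 4 lists in the 5 contrasts in the order above.

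Alternatives planned were RLE and upper-quartile scaling, DESeq2 1.42.0, limma voom with sample weights, robust edgeR, no filter, at least 10 counts in every library of a group, only the groups compared, a replicate block and each library left out in turn. Chosen after seeing the data were both PBS libraries high in Rag1 left out, and covariates of mean marker list log2 CPM. Tests on simulated data with 200 changed genes among 10918 recovered 58.0, 74.0, 96.0 and 93.8% of planted 1.5, 2, 3 and 4-fold changes in the neonatal response, with 8 false calls, and 36.0, 60.0, 86.0 and 87.5% in the difference of responses, with 6 false calls. There DESeq2 called 172 (13 false) and limma voom 170 (10 false). Camera (either correlation) and fry called 0 of 30 unchanged lists, but correlated lists were untested.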

Results

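CD4+ T cells, the helper lineage of T lymphocytes, were sorted from the lungs of C57BL/6NJ mice of both sexes 48 h after aspiration of Escherichia coli or phosphate-buffered saline (PBS). The mice were 5 days old (neonates) or 15 days old (juveniles) when they aspirated 2800000 colony-forming units or PBS alone. By its title, the series concerns DNA methylation and the pneumonia response of newborn CD4+ T cells, and its RNA counts were analysed. The 4 groups held 3 libraries each. Per the labels, each library was a separate pool of 3 neonatal or 2 juvenile mice, so n = 3 counts pools. Counts assigned to genes ran from 6035445 to 8129983 per library. The group means were 6694231 ± 624988 (SD) for neonatal PBS, 7518193 ± 621646 for neonatal E. coli, 6425491 ± 396531 for juvenile PBS and 7792580 ± 426714 for juvenile E. coli. At these depths a count of 0 allows up to 3 counts, or 0.374 to 0.494 CPM (counts scaled to library totals) depending on the library. Intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Of the 19434 genes counted, 4823 had 0 counts in all 12 libraries and 11062 passed the filter on low counts and were tested.

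Juvenile E. coli libraries lay apart from all others on principal component 1 (37.2% of variance), at 33.0 to 51.7 against -29.1 to 3.80 for the other 9 libraries. Component 2 (19.2%) separated the ages, with neonatal libraries at 7.20 to 26.2 and juvenile libraries at -37.4 to -4.38. Juvenile PBS library 2 stood furthest out on that component, at -37.4, and its correlations with the other 2 libraries of its group were 0.969 and 0.975, against 0.981 or more within the other groups. Transcripts that define the sorted cells were abundant in every group. The T cell receptor signalling chain Cd3e stood at 1609 ± 170.3, 1584 ± 83.8, 1875 ± 177 and 1622 ± 87.0 CPM (mean ± SD) in neonatal PBS, neonatal E. coli, juvenile PBS and juvenile E. coli libraries. The coreceptor Cd4 stood at 1133 ± 87.5, 1086 ± 16.1, 1298 ± 50.9 and 1082 ± 49.6 CPM.

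**Figure D1:**
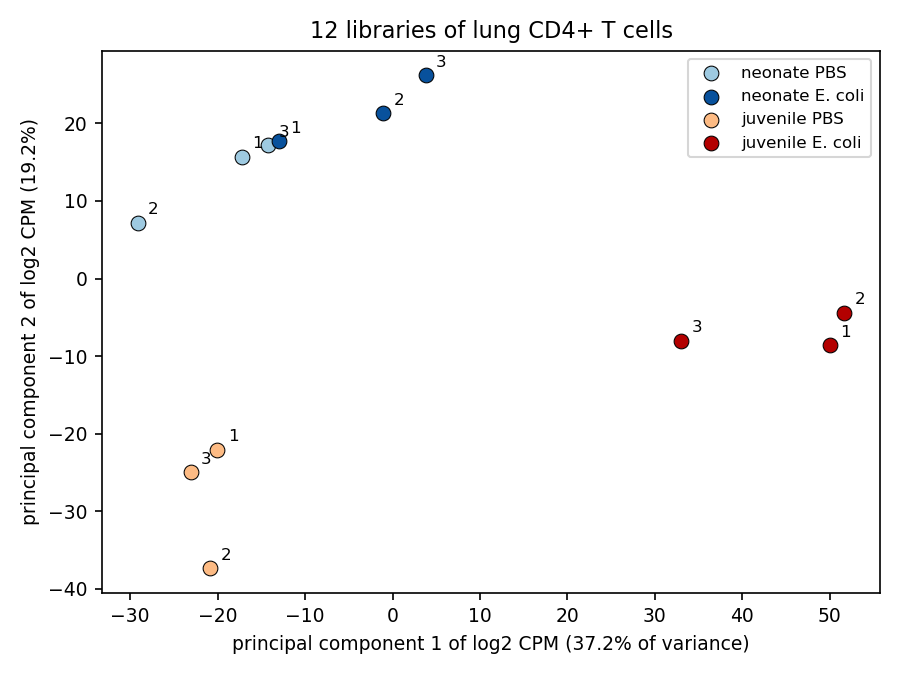
Principal components 1 and 2 (arbitrary units) of log2 CPM for the 12 libraries, 1 point per library, coloured by group and numbered by replicate. Juvenile E. coli libraries sit at 33.0 to 51.7 on component 1, right of all others, and neonatal libraries sit above juvenile ones on component 2.

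Transcripts typical of other cells were also counted and differed both between groups and between libraries of a group. Rag1, the recombinase of immature lymphocytes, stood at 344, 76.0 and 47.5 CPM in neonatal PBS libraries 1 to 3, 0.255, 42.8 and 8.49 in neonatal E. coli, 13.7, 169.9 and 29.5 in juvenile PBS and 104, 145 and 102 in juvenile E. coli. Cd8a, the coreceptor of cytotoxic T cells, was likewise highest in neonatal PBS library 1 (99.9 CPM) and juvenile PBS library 2 (63.3 CPM) among the PBS libraries. Summed over 10 neutrophil genes, expression was 2.57 ± 0.665 CPM in neonatal PBS, 50.5 ± 39.9 in neonatal E. coli, 4.46 ± 0.744 in juvenile PBS and 59.8 ± 19.6 in juvenile E. coli. The sum over 15 dendritic cell and MHC class II genes was 293 ± 50.4, 342 ± 14.2, 487 ± 41.1 and 1029 ± 146 CPM in the same order. The 13 lung epithelial genes summed to 108 ± 29.4, 150.4 ± 62.3, 65.7 ± 3.27 and 201 ± 63.6 CPM, and 11 fibroblast and smooth muscle genes to 124 ± 41.3, 128 ± 50.6, 51.4 ± 14.4 and 89.8 ± 15.4 CPM.

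**Figure D2:**
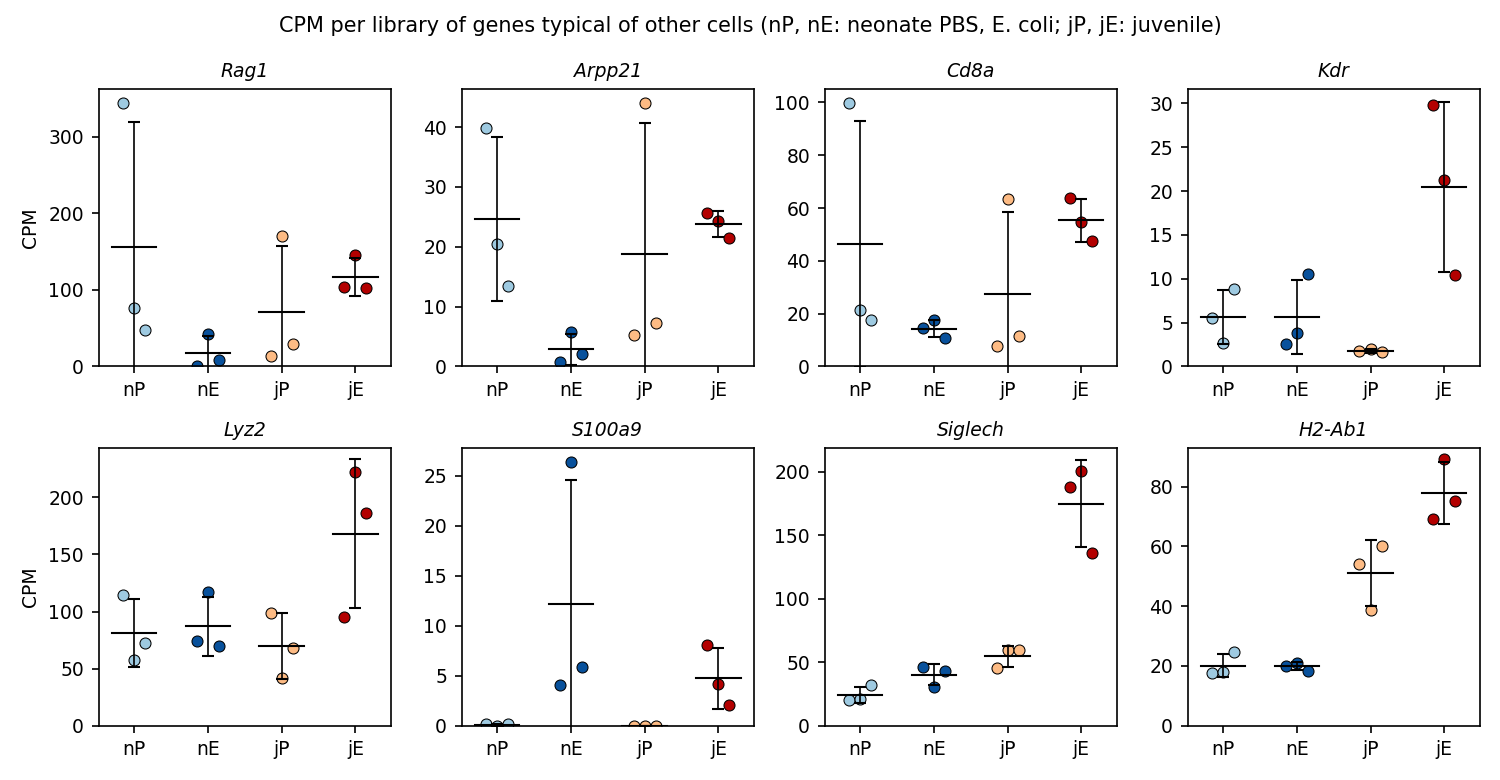
CPM per library (points) with group mean and SD (bars, drawn from 0 upward) of 8 genes typical of immature T cells (Rag1, Arpp21), CD8 T cells (Cd8a), endothelium (Kdr), myeloid cells (Lyz2, S100a9) and antigen-presenting cells (Siglech, H2-Ab1). Rag1 ran from 0.255 to 344 CPM, and Siglech and H2-Ab1 were higher in each juvenile E. coli library than in any other library.

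The neonatal response compared E. coli with PBS in mice that aspirated on day 5. Socs3 (chromosome 11, 117966079 to 117970047, GRCm38), a feedback inhibitor of JAK-STAT cytokine signalling, rose from 19.2 ± 4.42 to 100.4 ± 11.2 CPM, a log2 fold change of 2.38 ± 0.22 (± SE, n = 3 per group, adjusted p = 0.000222). Irf4, a transcription factor induced by T cell receptor signalling, rose by 2.02 ± 0.21, its partner Batf by 1.06 ± 0.15, and Bcl3, a nuclear IkB family protein, by 1.59 ± 0.17 on the log2 scale. Il17a, the signature cytokine of Th17 cells, had 0 counts in all 6 PBS libraries. It reached 1.39 ± 0.528 CPM in neonatal E. coli libraries, at least 3.08-fold higher against a floor of 3 counts per library (adjusted p = 0.0173). Ifng, the signature cytokine of Th1 cells, stood at 3.68 ± 0.313 CPM after PBS and 5.17 ± 1.30 CPM after E. coli (log2 0.48 ± 0.33, adjusted p = 0.642) and did not pass.

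In total 116 transcripts rose and 16 fell in neonates (edgeR quasi-likelihood test, adjusted p under 0.05), among 1327 with an unadjusted p under 0.05, and 73 of the rises and 2 of the falls were at least 2-fold. The 16 falls were 52 with DESeq2, 97 with limma voom, 90 with only the neonatal libraries, 9 with a replicate block, 2, 3 and 8 without PBS library 1, 2 or 3, and 6, 1 and 25 without E. coli library 1, 2 or 3. Besides Socs3, the largest rises were those of Hspa1b (3.25 ± 0.46), Irg1 (2.97 ± 0.51), Il1rn (2.79 ± 0.59), Hspa1a (2.64 ± 0.35), Cxcl2 (2.55 ± 0.54), Ptgs2 (2.43 ± 0.41) and Fcgr2b (2.26 ± 0.46). Hspa1a and Hspa1b are near-identical heat shock genes, so the split of reads between them is uncertain, and Irg1, Il1rn, Cxcl2 and Fcgr2b are best known from myeloid cells. The largest falls were those of the receptor Erbb3 (-1.13 ± 0.26), Nhsl2 (-0.91 ± 0.19), Myadm (-0.77 ± 0.15), the integrin chain Itgb1 (-0.66 ± 0.14), the stress-induced Sesn1 (-0.66 ± 0.13), Tbc1d4 (-0.63 ± 0.12), Usp28 (-0.59 ± 0.13) and Xkrx (-0.59 ± 0.11).

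Among the fixed gene lists in neonates, of 16 Th17 genes, 7 rose, 0 fell and 9 did not pass (12 and 1 adjusted over the list alone, camera adjusted p = 4.15e-17, adjusted p = 0.00589 with an estimated correlation). They included Batf, Stat3 (0.65 ± 0.10), Ahr (0.88 ± 0.15) and the cytokine Il22 (1.86 ± 0.30). Of 19 STAT target and cytokine feedback genes, 7 rose, 0 fell and 12 did not pass (11 and 1 adjusted over the list alone, camera adjusted p = 7.66e-20, adjusted p = 0.0115 with an estimated correlation), with Cish at 1.11 ± 0.17. Of 31 NF-kB target genes, 6 rose, 0 fell and 25 did not pass (15 and 0 adjusted over the list alone, camera adjusted p = 3.57e-16, adjusted p = 0.0115 with an estimated correlation), with the adhesion molecule Icam1 at 1.31 ± 0.13 and Nfkbiz at 0.76 ± 0.13. Of 32 immediate early and dissociation stress genes, 7 rose, 0 fell and 25 did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 4.02e-21, adjusted p = 0.0157 with an estimated correlation), with Rgs1 at 1.25 ± 0.14 and Jun at 1.23 ± 0.21. Of 32 T cell activation genes, 4 rose, 0 fell and 28 did not pass (15 and 1 adjusted over the list alone, camera adjusted p = 3.31e-09, adjusted p = 0.0365 with an estimated correlation), with Myc at 0.71 ± 0.12 and Pdcd1 at 1.17 ± 0.22. Of 11 NK cell and innate lymphoid cell genes, 3 rose, 0 fell and 8 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 8.38e-06, adjusted p = 0.0182 with an estimated correlation). Of 16 cytotoxic effector and CD8 T cell genes, 1 rose, 0 fell and 15 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.00295, adjusted p = 0.0343 with an estimated correlation), the riser being the chemokine Xcl1 (2.02 ± 0.40).

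Neutrophil genes moved with these groups, and of 10 genes, 7 rose, 0 fell and 3 did not pass (9 and 0 adjusted over the list alone, camera adjusted p = 2.83e-21, adjusted p = 0.0157 with an estimated correlation). S100a9, an abundant neutrophil protein, had 285 counts in neonatal E. coli against 2 in neonatal PBS libraries, a ratio of 125 (95% exact binomial interval 34.4 to 1040), and S100a8 had 184 against 1, a ratio of 162 (28.7 to 6420). The median log2 fold change of the neutrophil list was 4.63, or 3.96 with the member at 0 counts in PBS libraries placed at its bound. Of 23 monocyte and macrophage genes, 1 rose, 0 fell and 22 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 2.61e-06, adjusted p = 0.209 with an estimated correlation). Of 15 immature T cell and recent thymic emigrant genes, 0 rose, 0 fell and 15 did not pass (0 and 4 adjusted over the list alone, camera adjusted p = 0.0131, adjusted p = 0.487 with an estimated correlation).

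Of 25 lung homing and tissue residency genes, 3 rose, 3 fell and 19 did not pass (6 and 4 adjusted over the list alone, camera adjusted p = 0.0529, adjusted p = 0.654 with an estimated correlation). Of 12 follicular helper T cell genes, 2 rose, 0 fell and 10 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.0825, adjusted p = 0.209 with an estimated correlation). Of 49 interferon response genes, 1 rose, 0 fell and 48 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 0.00799, adjusted p = 0.717 with an estimated correlation), the riser being the transcription factor Irf1 (0.99 ± 0.20). Of 15 Th1 genes, 0 rose, 0 fell and 15 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 0.00515, adjusted p = 0.117 with an estimated correlation). Of 15 Th2 genes, 1 rose, 0 fell and 14 did not pass (3 and 1 adjusted over the list alone, camera adjusted p = 0.0387, adjusted p = 0.424 with an estimated correlation). Of 74 ribosomal protein genes, 0 rose, 0 fell and 74 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.0131, adjusted p = 0.739 with an estimated correlation). Of 45 cell cycle genes, 0 rose, 0 fell and 45 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.0803, adjusted p = 0.855 with an estimated correlation). Of 21 regulatory T cell genes, 0 rose, 0 fell and 21 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.867, adjusted p = 0.986 with an estimated correlation). Foxp3, the transcription factor of regulatory T cells, stood at 309.7 ± 8.70 and 219.9 ± 52.1 CPM and did not pass (log2 -0.50 ± 0.18, adjusted p = 0.260). The count of 132 calls was 235 with DESeq2, 312 with limma voom and 320 in a fit of the 6 neonatal libraries alone, and it was 56, 55 and 62 without neonatal PBS library 1, PBS library 2 or E. coli library 2. With monocyte, macrophage and neutrophil markers as a covariate, an alternative chosen after seeing the data, edgeR called 0 genes, with 447 at an unadjusted p under 0.05, and with immature T cell markers it called 75.

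The juvenile response made the same comparison in mice that aspirated on day 15. Ifng (chromosome 10, 118441046 to 118445892) rose from 5.04 ± 1.40 to 42.4 ± 15.9 CPM (log2 3.08 ± 0.28, n = 3 per group, adjusted p = 3.04e-06). Foxp3 (chromosome X, 7573644 to 7595245) rose from 338 ± 47.8 to 687 ± 187 CPM, Il2ra (chromosome 2, 11642807 to 11693193), the high-affinity chain of the IL-2 receptor, from 221 ± 32.6 to 684 ± 239, and the proliferation marker Mki67 (chromosome 7, 135689784 to 135716361) from 818 ± 297 to 2146 ± 348. Naive T cell genes fell, such as the homing receptor Ccr7 (-1.14 ± 0.14) and Il7r (-0.75 ± 0.10), as did most ribosomal protein genes. Neither list held with an estimated correlation.

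In total 1705 transcripts rose and 1042 fell in juveniles, of 4089 with an unadjusted p under 0.05, and 835 of the rises and 133 of the falls were at least 2-fold. Upper-quartile scaling moved the split to 1468 rises and 1415 falls, or 50.9% up against 62.1% with the main scaling. The 1042 falls were 1949 with limma voom, 608 with only the juvenile libraries, and 628 and 513 without E. coli library 1 or 2. The largest rises included the interferon-induced chemokines Cxcl9 (7.02 ± 0.55) and Cxcl10 (4.92 ± 0.43), Hspa1b (5.06 ± 0.53), Hspa1a (4.38 ± 0.40), Irg1 (4.53 ± 0.42), Il1rn (4.15 ± 0.51), Ptgs2 (3.91 ± 0.46) and the endothelial receptor Kdr (3.53 ± 0.55). Cxcl9 stood at 0.207 ± 0.245 CPM in juvenile PBS libraries, under the 3-count floor of 0.468 CPM, so the size of its change is imprecise. The largest falls were those of Chi3l3, a chitinase-like protein best known from lung macrophages (-4.06 ± 0.41), the Wnt antagonist Nkd2 (-2.56 ± 0.33), Sele (-1.74 ± 0.25), Tspan9 (-1.72 ± 0.25), the glucocorticoid-induced Tsc22d3 (-1.55 ± 0.16), Paqr7 (-1.41 ± 0.16), Slc26a10 (-1.40 ± 0.20) and Pex11c (-1.31 ± 0.17).

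Interferon response genes in juveniles moved nearly as a block, and of 49 genes, 46 rose, 1 fell and 2 did not pass (47 and 1 adjusted over the list alone, camera adjusted p = 8.23e-52, adjusted p = 0.0306 with an estimated correlation). Examples were the surface protein Ly6a (3.17 ± 0.22) and the guanylate-binding protein Gbp5 (2.80 ± 0.20). Of 15 Th1 genes, 13 rose, 0 fell and 2 did not pass (13 and 0 adjusted over the list alone, camera adjusted p = 6.98e-15, adjusted p = 0.00460 with an estimated correlation), with the IL-12 receptor chain Il12rb1 at 2.05 ± 0.19 and the transcription factor Tbx21 at 1.84 ± 0.22. Of 16 Th17 genes, 15 rose, 0 fell and 1 did not pass (15 and 0 adjusted over the list alone, camera adjusted p = 1.10e-15, adjusted p = 0.00460 with an estimated correlation). Il17a reached 2.65 ± 0.447 CPM, at least 5.67-fold higher against the floor of 3 counts per library, and Il22 had 169 counts in juvenile E. coli against 2 in juvenile PBS libraries, a ratio of 70.6 (95% exact binomial interval 19.3 to 588). Of 15 Th2 genes, 7 rose, 0 fell and 8 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 0.000222, adjusted p = 0.125 with an estimated correlation). The Th2 cytokine Il13 rose by 2.93 ± 0.75, whereas Il4 (log2 1.75 ± 0.69, adjusted p = 0.0766) and the transcription factor Gata3 (-0.23 ± 0.093, adjusted p = 0.0793) did not pass.

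Of 21 regulatory T cell genes, 18 rose, 1 fell and 2 did not pass (18 and 1 adjusted over the list alone, camera adjusted p = 1.09e-12, adjusted p = 0.0701 with an estimated correlation). The risers included Ctla4 (1.79 ± 0.17), the ectonucleotidase Entpd1 (2.09 ± 0.19) and the cytokine Il10 (2.70 ± 0.34), while Gpr83 fell by 0.88. Of 32 T cell activation genes, 25 rose, 1 fell and 6 did not pass (25 and 1 adjusted over the list alone, camera adjusted p = 2.03e-19, adjusted p = 0.00602 with an estimated correlation). The transcription factors Prdm1 (2.15 ± 0.15) and Irf4 (2.50 ± 0.21) and the adhesion receptor Cd44 (0.84 ± 0.10) rose. Of 20 naive T cell and lymph node homing genes, 0 rose, 20 fell and 0 did not pass (0 and 20 adjusted over the list alone, camera adjusted p = 1.78e-16, adjusted p = 0.0701 with an estimated correlation). Of 21 T cell identity genes, 0 rose, 9 fell and 12 did not pass (0 and 11 adjusted over the list alone, camera adjusted p = 1.22e-05, adjusted p = 0.0988 with an estimated correlation), with Cd3d at -0.76 ± 0.12 and Cd4 at -0.26 ± 0.072. Of 45 cell cycle genes, 31 rose, 0 fell and 14 did not pass (36 and 0 adjusted over the list alone, camera adjusted p = 2.39e-14, adjusted p = 0.215 with an estimated correlation), with the kinesin Cenpe at 1.56 ± 0.19. Of 25 lung homing and tissue residency genes, 14 rose, 2 fell and 9 did not pass (14 and 2 adjusted over the list alone, camera adjusted p = 3.66e-07, adjusted p = 0.113 with an estimated correlation), with the chemokine receptor Cxcr3 at 1.51 ± 0.18.

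Of 31 NF-kB target genes, 22 rose, 0 fell and 9 did not pass (23 and 1 adjusted over the list alone, camera adjusted p = 1.22e-15, adjusted p = 0.00602 with an estimated correlation), with Icam1 at 2.42 ± 0.13. Of 19 STAT target and cytokine feedback genes, 10 rose, 1 fell and 8 did not pass (12 and 1 adjusted over the list alone, camera adjusted p = 7.00e-09, adjusted p = 0.0425 with an estimated correlation), with Socs3 at 2.44 ± 0.23. Of 32 immediate early and dissociation stress genes, 11 rose, 1 fell and 20 did not pass (11 and 1 adjusted over the list alone, camera adjusted p = 0.000651, adjusted p = 0.228 with an estimated correlation). Of 16 cytotoxic effector and CD8 T cell genes, 7 rose, 1 fell and 8 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 2.82e-05, adjusted p = 0.0106 with an estimated correlation), with granzyme B (Gzmb) at 3.45 ± 0.43. Of 74 ribosomal protein genes, 0 rose, 67 fell and 7 did not pass (0 and 71 adjusted over the list alone, camera adjusted p = 3.24e-29, adjusted p = 0.0872 with an estimated correlation), with Rpl8 at -0.68 ± 0.092. The summed expression of the ribosomal list was 39560, 52680 and 39430 CPM in juvenile PBS libraries 1 to 3 and 29650 ± 2198 CPM in juvenile E. coli libraries, and processed pseudogenes of these genes make their single values uncertain.

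Markers of other cells moved in juveniles too. Of 10 neutrophil genes, 9 rose, 0 fell and 1 did not pass (10 and 0 adjusted over the list alone, camera adjusted p = 3.08e-08, adjusted p = 0.0872 with an estimated correlation). Their median was 6.31, or 2.60 with 5 members at 0 counts in PBS libraries placed at their bounds. Of 15 dendritic cell and MHC class II genes, 9 rose, 0 fell and 6 did not pass (10 and 0 adjusted over the list alone, camera adjusted p = 0.000239, adjusted p = 0.0306 with an estimated correlation), with Siglech, a receptor of plasmacytoid dendritic cells, at 1.68 ± 0.19 and the invariant chain Cd74 at 0.95 ± 0.22. Of 23 monocyte and macrophage genes, 14 rose, 2 fell and 7 did not pass (17 and 2 adjusted over the list alone, camera adjusted p = 0.000562, adjusted p = 0.276 with an estimated correlation), with Ccr2 at 1.67 ± 0.20. Of 11 NK cell and innate lymphoid cell genes, 6 rose, 0 fell and 5 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 0.000306, adjusted p = 0.0499 with an estimated correlation). Of 13 endothelial genes, 6 rose, 2 fell and 5 did not pass (9 and 2 adjusted over the list alone, camera adjusted p = 0.0286, adjusted p = 0.492 with an estimated correlation). The median was 2.18 (1.98 with a member at its bound), but the sum did not rise (431 ± 23.6 to 407 ± 4.52 CPM). Of 13 lung epithelial genes, 3 rose, 0 fell and 10 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.00482, adjusted p = 0.276 with an estimated correlation). The count of 2747 calls was 4480 with limma voom and 1799 and 1656 without juvenile E. coli library 1 or 2. With marker covariates chosen after seeing the data it was 718 (endothelial and fibroblast) and 16 (monocyte, macrophage and neutrophil). The design alone widened the SE 1.42 and 2.36-fold. In these 2 fits the median change was 1.73 and 1.75 for interferon response genes (1.65 without a covariate), 1.07 and 1.20 for Th1 genes (1.10), 0.79 and 1.35 for regulatory T cell genes (1.02) and -0.42 and -0.073 for ribosomal protein genes (-0.61).

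The responses at the 2 ages, which share no library, were set side by side. Socs3 rose at both ages, by 2.38 ± 0.22 in neonates and 2.44 ± 0.23 in juveniles, and Irf4 by 2.02 ± 0.21 and 2.50 ± 0.21. Of the 116 rises in neonates, 103 were also rises in juveniles, where independent lists would share 17.9, and of the 16 falls 6 were shared where 1.51 would be. The other shared calls were 4 transcripts that moved in opposite directions. Among the 113 called at both ages, 82 changed more in juveniles, and the median ratio of the neonatal to the juvenile log2 change was 0.760. Over all genes called in juveniles the slope of neonatal on juvenile change was 0.306, and 65.8% had the same sign. Across all tested genes, which are not independent replicates, the log2 changes correlated at Pearson r = 0.411 and Spearman rho = 0.218. The 109 calls shared in direction were 168 with DESeq2 and 49, 48 and 54 without neonatal PBS library 1, PBS library 2 or E. coli library 2. With covariates chosen after seeing the data they were 65 (immature T cell markers) and 0 (monocyte, macrophage and neutrophil markers, a fit in which edgeR called 0 genes in neonates).

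**Figure D3:**
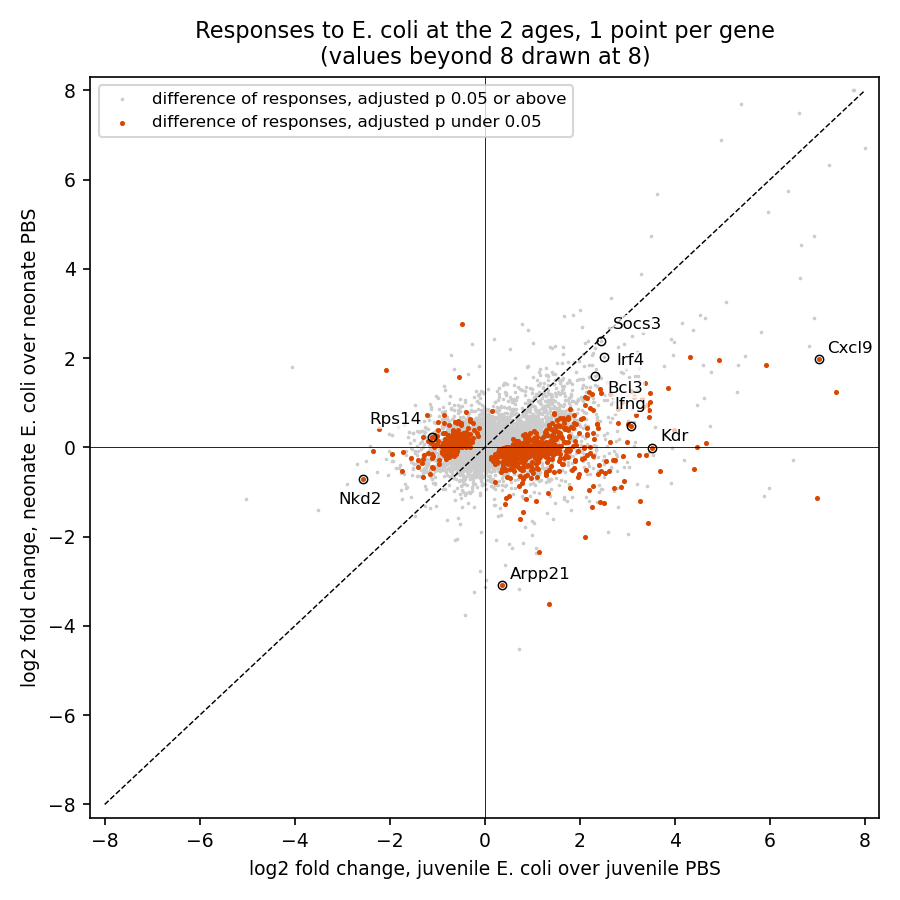
Log2 fold change after E. coli in juveniles (horizontal) and neonates (vertical), 1 point per tested gene, with orange points where the difference of responses passed and a dashed line of equal change. Socs3 lies near the dashed line (2.44 and 2.38), and points of genes with 0 counts in a group are fitted values that set no bound.

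The difference of responses (neonatal minus juvenile log2 fold change) is negative where neonates rose less or fell more. It was -2.60 ± 0.44 for Ifng (adjusted p = 0.00318), -2.01 ± 0.29 for Il2ra (0.00137), -1.52 ± 0.25 for Foxp3 (0.00287) and -1.81 ± 0.27 for Mki67 (0.00157). All 4 rose in juveniles and none passed in neonates (Il2ra 294 ± 16.7 to 225 ± 56.6 CPM). The cell cycle sum began higher in neonates, at 9081 and 8346 CPM (PBS, E. coli) against 5450 and 9416. Differences were positive for the naive T cell genes Ccr7 (1.24 ± 0.20) and Igfbp4 (1.04 ± 0.12). Tbx21 (-1.11 ± 0.34, adjusted p = 0.0643), Cd44 (-0.48 ± 0.14, 0.0576) and Il10 (-1.61 ± 0.66, 0.163) did not pass.

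In total 559 differences were negative and 215 positive, among 2455 with an unadjusted p under 0.05, and 329 and 46 of these were at least 2-fold. Upper-quartile scaling moved the split to 476 negative and 283 positive, or 37.3% positive against 27.8% with the main scaling. The 215 positive differences were 924 with limma voom, 109 and 121 without neonatal PBS library 1 or 3, 95 and 124 without neonatal E. coli library 1 or 2, 547 without juvenile PBS library 2, and 102, 70 and 402 without juvenile E. coli library 1, 2 or 3. Of the 774 genes, 728 were called in juveniles and 32 in neonates. The log2 changes at the 2 ages had opposite signs in 506, the same sign with a smaller neonatal change in 267, and the same sign with a larger neonatal change in 1. The most negative differences were those of Cxcl9 (-5.05 ± 1.18), Kdr (-3.53 ± 0.77), Arpp21 (-3.44 ± 0.96), Cav1 (-3.14 ± 0.89), Scn7a (-3.14 ± 0.86), Phf11 (-3.09 ± 0.52), Gpr116 (-3.03 ± 0.86) and the interferon-induced Ifit3 (-2.99 ± 0.43). Kdr, Cav1 and Gpr116 are typical of endothelium, and Arpp21 moved with Rag1 between libraries of a group, at 39.9, 20.4 and 13.4 CPM in neonatal PBS and 5.33, 44.0 and 7.17 CPM in juvenile PBS libraries. The most positive were those of Nkd2 (1.85 ± 0.45), Tspan9 (1.62 ± 0.35), Slc10a1 (1.56 ± 0.37), Amigo2 (1.54 ± 0.18), Gabrr2 (1.39 ± 0.29), the adaptor Hcst (1.39 ± 0.30), Rps14 (1.35 ± 0.28) and Slc16a5 (1.33 ± 0.24).

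By list, of 49 interferon response genes, 35 had a negative and 0 a positive difference and 14 did not pass (41 and 0 adjusted over the list alone, camera adjusted p = 4.80e-46, adjusted p = 0.0807 with an estimated correlation), with Parp14 at -1.18 ± 0.14 and Gbp6 at -2.07 ± 0.24. Of 15 Th1 genes, 6 had a negative and 0 a positive difference and 9 did not pass (9 and 0 adjusted over the list alone, camera adjusted p = 2.17e-09, adjusted p = 0.0365 with an estimated correlation), with Cxcr3 at -1.64 ± 0.27. Of 16 Th17 genes, 4 had a negative and 0 a positive difference and 12 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 4.50e-05, adjusted p = 0.0836 with an estimated correlation), with Maf at -0.89 ± 0.17 and Rora at -0.87 ± 0.18. Of 15 Th2 genes, 3 had a negative and 0 a positive difference and 12 did not pass (3 and 0 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.356 with an estimated correlation). Of 21 regulatory T cell genes, 12 had a negative and 1 a positive difference and 8 did not pass (17 and 1 adjusted over the list alone, camera adjusted p = 4.84e-14, adjusted p = 0.0893 with an estimated correlation), with Ctla4 at -1.86 ± 0.24 and Gpr83 at 1.20 ± 0.15. Of 32 T cell activation genes, 10 had a negative and 0 a positive difference and 22 did not pass (15 and 0 adjusted over the list alone, camera adjusted p = 7.82e-10, adjusted p = 0.0807 with an estimated correlation), with Prdm1 at -1.72 ± 0.21. Of 45 cell cycle genes, 20 had a negative and 0 a positive difference and 25 did not pass (32 and 0 adjusted over the list alone, camera adjusted p = 4.40e-20, adjusted p = 0.203 with an estimated correlation), with Cenpe at -1.86 ± 0.27. Of 25 lung homing and tissue residency genes, 7 had a negative and 1 a positive difference and 17 did not pass (9 and 2 adjusted over the list alone, camera adjusted p = 4.50e-05, adjusted p = 0.228 with an estimated correlation), with Anxa2 at -1.28 ± 0.20. Of 31 NF-kB target genes, 5 had a negative and 0 a positive difference and 26 did not pass (10 and 0 adjusted over the list alone, camera adjusted p = 0.000150, adjusted p = 0.103 with an estimated correlation). Of 16 cytotoxic effector and CD8 T cell genes, 3 had a negative and 0 a positive difference and 13 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.0265, adjusted p = 0.103 with an estimated correlation).

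Camera called 4 lists in the positive direction, those of naive T cells, ribosomal proteins, T cell identity and oxidative phosphorylation, where 0 of 43 genes passed. Of 20 naive T cell and lymph node homing genes, 0 had a negative and 12 a positive difference and 8 did not pass (0 and 18 adjusted over the list alone, camera adjusted p = 7.78e-18, adjusted p = 0.0981 with an estimated correlation). Of 74 ribosomal protein genes, 0 had a negative and 44 a positive difference and 30 did not pass (0 and 66 adjusted over the list alone, camera adjusted p = 8.20e-41, adjusted p = 0.0893 with an estimated correlation), with Rpl8 at 0.91 ± 0.13. Of 21 T cell identity genes, 0 had a negative and 3 a positive difference and 18 did not pass (0 and 5 adjusted over the list alone, camera adjusted p = 0.000283, adjusted p = 0.203 with an estimated correlation). Marker lists of other cells moved too. Of 13 endothelial genes, 2 had a negative and 0 a positive difference and 11 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.000586, adjusted p = 0.362 with an estimated correlation). Of 13 lung epithelial genes, 2 had a negative and 0 a positive difference and 11 did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 0.00521, adjusted p = 0.374 with an estimated correlation). Of 15 dendritic cell and MHC class II genes, 1 had a negative and 0 a positive difference and 14 did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 0.0113, adjusted p = 0.103 with an estimated correlation). Of 15 immature T cell and recent thymic emigrant genes, 2 had a negative and 0 a positive difference and 13 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.510 with an estimated correlation). Of the 19 lists camera called, the Th1 list alone held with an estimated correlation.

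The count of 774 was 2300 with limma voom. Without single libraries it was 408 and 450 for neonatal PBS library 1 or 3, 372 and 433 for neonatal E. coli library 1 or 2, 504 and 1553 for juvenile PBS library 1 or 2, and 368, 368 and 1163 for juvenile E. coli library 1, 2 or 3. With covariates chosen after seeing the data it was 15 (immature T cell markers) and 57 (endothelial and fibroblast markers), where the design alone widened the SE by factors of 1.36 and 1.32. In these 2 fits the median difference was -1.34 and -1.55 for interferon response genes (-1.45 without a covariate), -1.09 and -1.09 for regulatory T cell genes (-1.15) and -0.44 and -0.84 for cell cycle genes (-0.84).

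**Figure D4:**
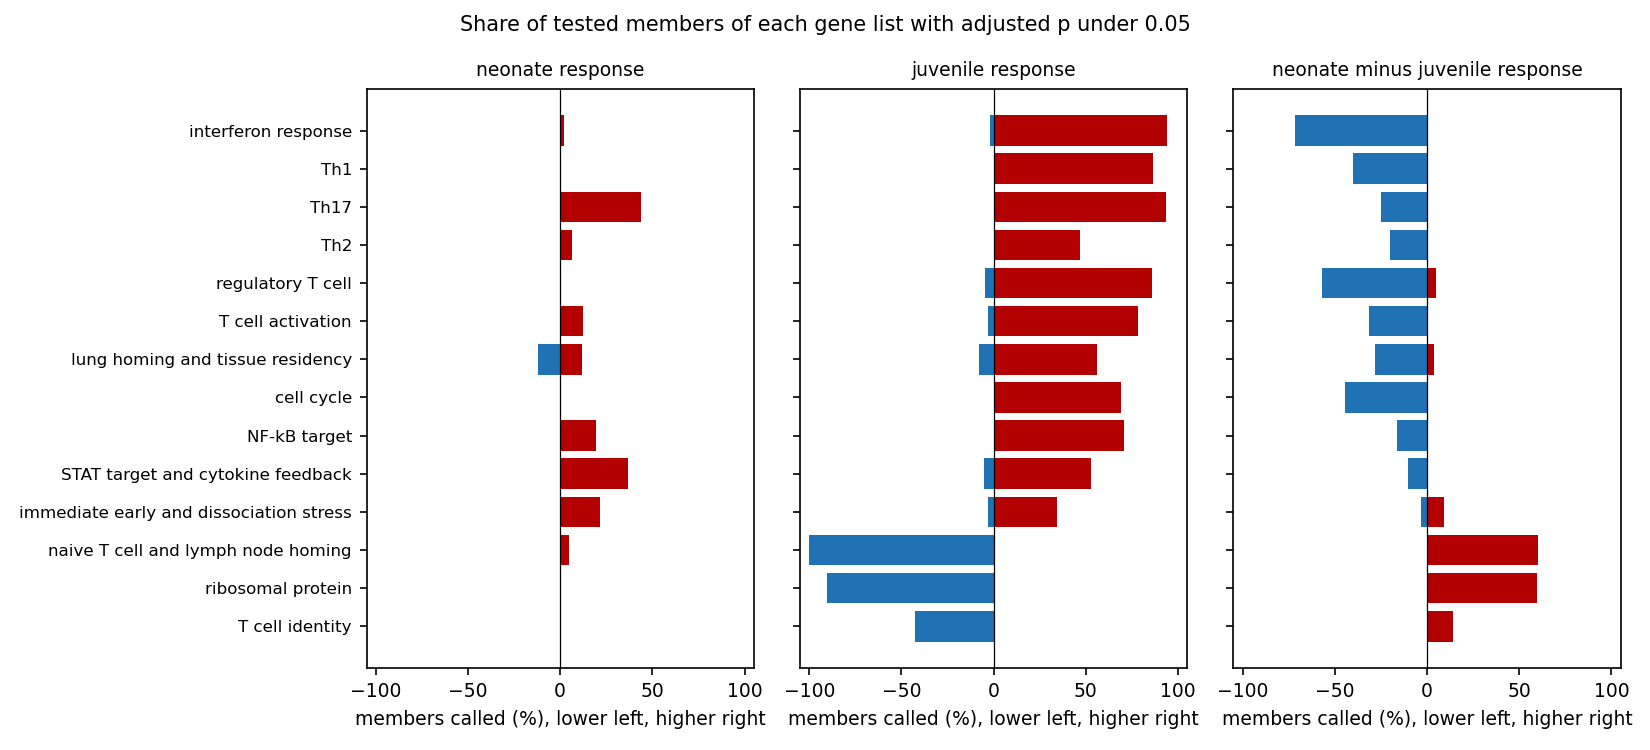
Percent of tested members of 14 gene lists called lower (bars to the left) or higher (to the right) in the neonatal response, the juvenile response and the neonatal minus juvenile difference. For interferon response genes 46 of 49 rose in juveniles, 1 of 49 in neonates, and 35 of 49 had a negative difference.

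**Figure D5:**
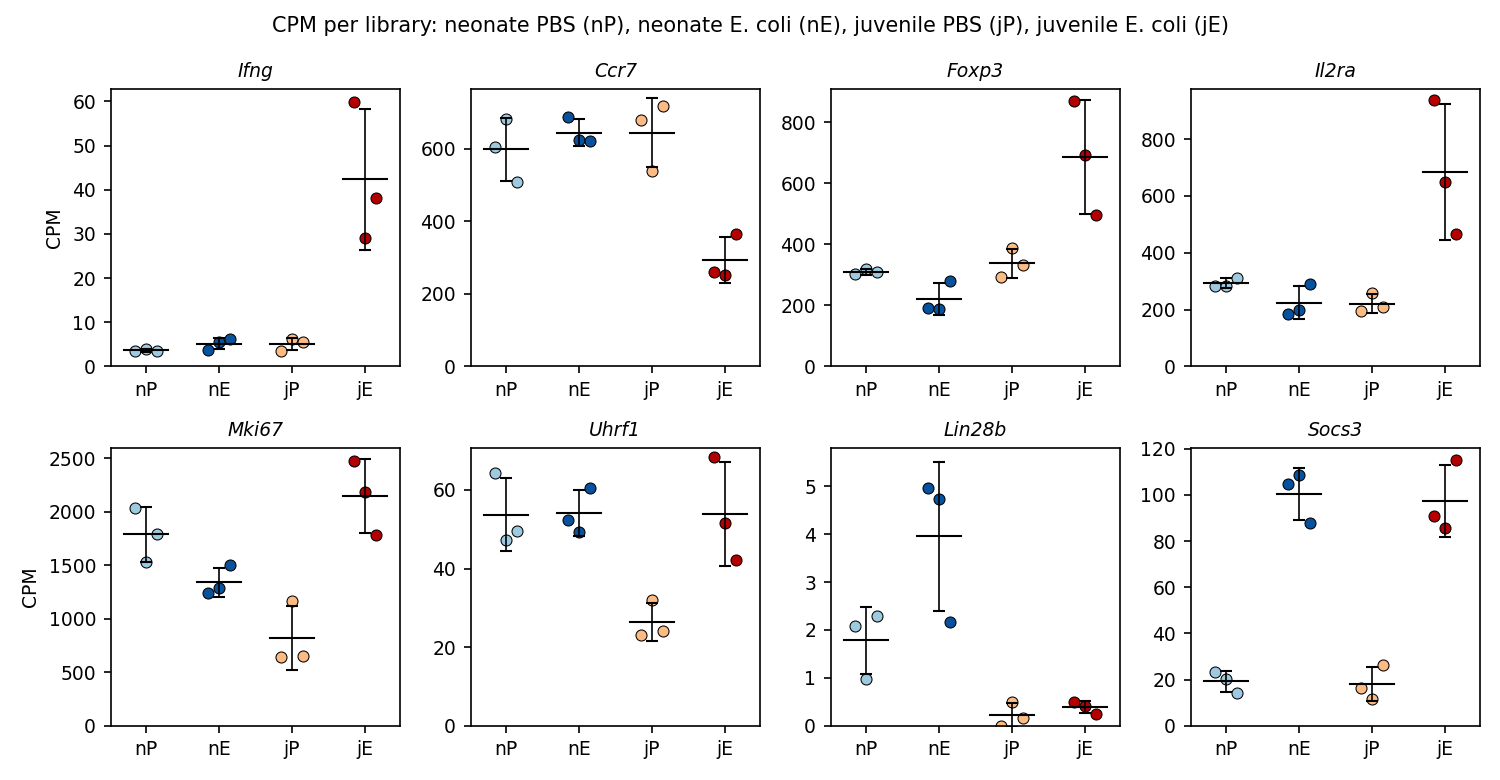
CPM per library (points) with group mean and SD (bars, drawn from 0 upward) of Ifng, Ccr7, Foxp3, Il2ra, Mki67, Uhrf1, Lin28b and Socs3 in the 4 groups. Ifng, Foxp3 and Il2ra are highest in the juvenile E. coli libraries, Lin28b in the neonatal libraries, and Socs3 in the E. coli libraries of both ages.

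DNA methylation genes were tested as a list of 24. In neonates 1 rose, 0 fell and 23 did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 0.867, adjusted p = 0.955 with an estimated correlation), the riser being the stress-induced Gadd45g (2.25 ± 0.43). In juveniles 5 rose, 2 fell and 17 did not pass (5 and 2 adjusted over the list alone, camera adjusted p = 0.662, adjusted p = 0.658 with an estimated correlation). Uhrf1 (chromosome 17, 56303321 to 56323486), the cofactor that guides maintenance methylation, rose by 1.04 ± 0.18 in juveniles, and the maintenance methyltransferase Dnmt1 by 0.47 ± 0.13, while Tet1 (chromosome 10, 62804570 to 62908996), an enzyme that oxidises methylcytosine, fell by 0.77. The difference of responses was -1.03 ± 0.25 for Uhrf1 (adjusted p = 0.0239), 0.54 ± 0.11 for Tet1 (0.0101) and -0.55 ± 0.18 for Dnmt1 (0.0845, not passed). In the whole list 1 had a negative and 2 a positive difference and 21 did not pass (1 and 2 adjusted over the list alone, camera adjusted p = 0.753, adjusted p = 0.733 with an estimated correlation). The de novo methyltransferases Dnmt3a (0.20 ± 0.087 in neonates, 0.11 ± 0.088 in juveniles) and Dnmt3b (0.093 ± 0.17 and -0.35 ± 0.18) did not pass in either response. Tet2 rose in juveniles by 0.28 ± 0.078, and Tet3 stood at 0.013 ± 0.13 and -0.25 ± 0.13 without passing. Uhrf1 was also higher in neonatal than juvenile PBS libraries (log2 1.03 ± 0.18), where of the list 1 was higher and 0 lower in neonates and 23 did not pass (4 and 2 adjusted over the list alone, camera adjusted p = 0.0809, adjusted p = 0.234 with an estimated correlation). Cell cycle medians moved with Uhrf1 (juveniles 0.71, difference -0.84, PBS 0.76), so proliferation is not told apart.

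Age after PBS compared unchallenged neonatal with juvenile cells, with positive values higher in neonates. Mki67 stood at 1787 ± 256 CPM in neonates and 818 ± 297 in juveniles (log2 1.13 ± 0.19, n = 3 per group, adjusted p = 0.00420). The RNA-binding proteins of fetal lymphopoiesis Lin28b (chromosome 10, 45376620 to 45486395) and Igf2bp3 (chromosome 6, 49085223 to 49214957) were higher in neonates by 2.98 ± 0.75 and 0.57 ± 0.082, with Lin28b in juveniles (0.218 ± 0.252 CPM) under the 3-count floor of 0.468 CPM. The imprinted growth regulator Grb10 (chromosome 11, 11930508 to 12038683) was higher by 2.83 ± 0.54. Klrg1 (chromosome 6, 122270596 to 122282882), a receptor of differentiated effector cells, was lower in neonates (29.9 ± 2.06 against 132 ± 32.8 CPM, log2 -2.14 ± 0.30), as were Il10 (-2.09 ± 0.49) and Cd44 (-0.84 ± 0.10).

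In total 257 transcripts were higher and 194 lower in neonates after PBS, among 1973 with an unadjusted p under 0.05, and 121 and 71 of these by at least 2-fold. Besides Grb10, the largest positive values were those of Scn7a (2.49 ± 0.66), Thbs1 (2.37 ± 0.56), Cd93 (1.95 ± 0.34), the stem cell factor receptor Kit (1.74 ± 0.35), Tln2 (1.68 ± 0.17), Stc2 (1.51 ± 0.24) and the cell cycle inhibitor Cdkn1a (1.505 ± 0.27). Chi3l3 had 643 counts in juvenile against 1 in neonatal PBS libraries, a ratio of 669 (95% exact binomial interval 120 to 26400). The other large negative values were those of Fgl2 (-2.46 ± 0.26), Hlf (-2.25 ± 0.42), Ctla2a (-2.20 ± 0.43), the IL-33 receptor Il1rl1 (-2.11 ± 0.35) and the chemokine Ccl5 (-1.96 ± 0.29).

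Of 45 cell cycle genes after PBS, 24 were higher and 0 lower in neonates and 21 did not pass (40 and 0 adjusted over the list alone, camera adjusted p = 1.11e-40, adjusted p = 0.102 with an estimated correlation). Of 14 fetal and neonatal program genes, 4 were higher and 0 lower in neonates and 10 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.000117, adjusted p = 0.102 with an estimated correlation). Of 20 naive T cell and lymph node homing genes, 0 were higher and 2 lower in neonates and 18 did not pass (0 and 4 adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.592 with an estimated correlation). Of 21 T cell identity genes, 0 were higher and 0 lower in neonates and 21 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.0443, adjusted p = 0.471 with an estimated correlation). Of 15 Th2 genes, 0 were higher and 5 lower in neonates and 10 did not pass (0 and 6 adjusted over the list alone, camera adjusted p = 8.36e-05, adjusted p = 0.174 with an estimated correlation). Of 16 Th17 genes, 3 were higher and 2 lower in neonates and 11 did not pass (5 and 2 adjusted over the list alone, camera adjusted p = 0.0141, adjusted p = 0.244 with an estimated correlation). Il22 had 71 counts in neonatal against 2 in juvenile PBS libraries, a ratio of 34.1 (95% exact binomial interval 9.11 to 287). Of 25 lung homing and tissue residency genes, 2 were higher and 6 lower in neonates and 17 did not pass (2 and 9 adjusted over the list alone, camera adjusted p = 5.25e-06, adjusted p = 0.234 with an estimated correlation), with Cd69 at -0.91 ± 0.098 and Cxcr6 at -1.32 ± 0.15. Of 16 cytotoxic effector and CD8 T cell genes, 0 were higher and 3 lower in neonates and 13 did not pass (1 and 8 adjusted over the list alone, camera adjusted p = 0.000579, adjusted p = 0.0645 with an estimated correlation). Of 74 ribosomal protein genes, 0 were higher and 5 lower in neonates and 69 did not pass (0 and 22 adjusted over the list alone, camera adjusted p = 5.15e-11, adjusted p = 0.347 with an estimated correlation).

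Markers of other cells differed by age after PBS too. Of 15 dendritic cell and MHC class II genes, 0 were higher and 7 lower in neonates and 8 did not pass (0 and 9 adjusted over the list alone, camera adjusted p = 2.33e-13, adjusted p = 0.00162 with an estimated correlation), with the antigen-presenting molecule H2-Ab1 at -1.35 ± 0.17 and Cd209a at -2.96 ± 0.32. Of the 17 lists camera called, it alone held with an estimated correlation. Of 13 endothelial genes, 1 was higher and 0 lower in neonates and 12 did not pass (9 and 0 adjusted over the list alone, camera adjusted p = 7.12e-06, adjusted p = 0.254 with an estimated correlation). Of 13 lung epithelial genes, 3 were higher and 0 lower in neonates and 10 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 0.000278, adjusted p = 0.257 with an estimated correlation). Of 11 fibroblast and smooth muscle genes, 1 was higher and 0 lower in neonates and 10 did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 7.12e-06, adjusted p = 0.103 with an estimated correlation). Of 11 NK cell and innate lymphoid cell genes, 1 was higher and 4 lower in neonates and 6 did not pass (1 and 7 adjusted over the list alone, camera adjusted p = 3.80e-05, adjusted p = 0.0645 with an estimated correlation). Of 23 monocyte and macrophage genes, 1 was higher and 4 lower in neonates and 18 did not pass (2 and 6 adjusted over the list alone, camera adjusted p = 0.000120, adjusted p = 0.299 with an estimated correlation). The count of 451 was 702 with DESeq2, 927 with limma voom and 280 in a fit of the 6 PBS libraries alone, and it was 177 and 299 without neonatal PBS library 1 or 2 and 243 without juvenile PBS library 1. With covariates chosen after seeing the data it was 70 (endothelial and fibroblast markers) and 283 (monocyte, macrophage and neutrophil markers), with the SE widened by the design by factors of 1.46 and 1.15.

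Age after E. coli compared cells of neonates with cells of juveniles that had aspirated E. coli. Interferon-induced transcripts were lower in neonates, among them Iigp1 (22.2 ± 4.32 against 217 ± 96.2 CPM, log2 -3.28 ± 0.27, n = 3 per group, adjusted p = 1.26e-06), Cxcl9 (-4.001 ± 0.39) and Mx1 (-3.15 ± 0.39). Ifng (-3.04 ± 0.27), Il10 (-3.70 ± 0.37), Foxp3 (-1.64 ± 0.18), Il2ra (-1.60 ± 0.21) and Tbx21 (-1.86 ± 0.22) were lower in neonates as well, and so was Klrg1 (16.6 ± 11.9 against 216 ± 37.4 CPM, log2 -3.72 ± 0.32). Higher in neonates were Grb10 (2.24 ± 0.45), Lin28b (3.29 ± 0.59), Igf2bp3 (0.78 ± 0.082), Dnmt3b (0.84 ± 0.17), Tet1 (0.42 ± 0.080) and the naive T cell transcription factor Tcf7 (0.81 ± 0.099). Il17a did not pass between the ages (1.39 ± 0.528 and 2.65 ± 0.447 CPM, log2 -0.92 ± 0.46, adjusted p = 0.201).

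In total 710 transcripts were higher and 1254 lower in neonates after E. coli, among 3415 with an unadjusted p under 0.05, and 94 and 582 of these by at least 2-fold. The split was 887 and 1099 with upper-quartile scaling and 1719 and 2091 with limma voom, and the 710 were 307 and 383 without neonatal and 279 and 283 without juvenile E. coli library 1 or 2. Further large positive values were those of Tln2 (1.60 ± 0.16), Stc2 (1.46 ± 0.23), Dnalc1 (1.42 ± 0.25), Gpr83 (1.39 ± 0.11), Tubb2a (1.38 ± 0.24), Lars2 (1.34 ± 0.22) and Gsta4 (1.28 ± 0.14). Further negative ones were those of Dntt (-3.37 ± 0.95), Frmd5 (-3.25 ± 0.30) and Ccr3 (-3.10 ± 0.41). Dntt, the terminal transferase of immature lymphocytes, belongs to the genes that varied with Rag1 between libraries.

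Of 49 interferon response genes after E. coli, 0 were higher and 46 lower in neonates and 3 did not pass (0 and 46 adjusted over the list alone, camera adjusted p = 1.96e-61, adjusted p = 0.0257 with an estimated correlation). Of 15 Th1 genes, 1 was higher and 9 lower in neonates and 5 did not pass (1 and 10 adjusted over the list alone, camera adjusted p = 1.10e-14, adjusted p = 0.00381 with an estimated correlation). Of 15 Th2 genes, 0 were higher and 9 lower in neonates and 6 did not pass (1 and 9 adjusted over the list alone, camera adjusted p = 2.51e-08, adjusted p = 0.0290 with an estimated correlation). Of 16 Th17 genes, 1 was higher and 4 lower in neonates and 11 did not pass (1 and 5 adjusted over the list alone, camera adjusted p = 0.0398, adjusted p = 0.268 with an estimated correlation). Of 31 NF-kB target genes, 0 were higher and 8 lower in neonates and 23 did not pass (0 and 11 adjusted over the list alone, camera adjusted p = 0.00538, adjusted p = 0.210 with an estimated correlation). Of 21 T cell identity genes, 4 were higher and 1 lower in neonates and 16 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.0275, adjusted p = 0.469 with an estimated correlation). Of 21 regulatory T cell genes, 1 was higher and 18 lower in neonates and 2 did not pass (2 and 18 adjusted over the list alone, camera adjusted p = 8.07e-19, adjusted p = 0.0290 with an estimated correlation). Of 32 T cell activation genes, 0 were higher and 16 lower in neonates and 16 did not pass (0 and 18 adjusted over the list alone, camera adjusted p = 1.37e-12, adjusted p = 0.0257 with an estimated correlation). Of 25 lung homing and tissue residency genes, 1 was higher and 15 lower in neonates and 9 did not pass (1 and 16 adjusted over the list alone, camera adjusted p = 1.17e-14, adjusted p = 0.0290 with an estimated correlation). Of 16 cytotoxic effector and CD8 T cell genes, 0 were higher and 7 lower in neonates and 9 did not pass (0 and 9 adjusted over the list alone, camera adjusted p = 8.25e-08, adjusted p = 0.00381 with an estimated correlation). Of 20 naive T cell and lymph node homing genes, 13 were higher and 1 lower in neonates and 6 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 1.03e-12, adjusted p = 0.132 with an estimated correlation). Of 74 ribosomal protein genes, 40 were higher and 0 lower in neonates and 34 did not pass (49 and 0 adjusted over the list alone, camera adjusted p = 1.61e-19, adjusted p = 0.201 with an estimated correlation). Of 14 fetal and neonatal program genes, 5 were higher and 1 lower in neonates and 8 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.00233, adjusted p = 0.0937 with an estimated correlation). Of 45 cell cycle genes, 1 was higher and 2 lower in neonates and 42 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.856, adjusted p = 0.999 with an estimated correlation).

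Beside these, of 15 dendritic cell and MHC class II genes after E. coli, 0 were higher and 13 lower in neonates and 2 did not pass (0 and 14 adjusted over the list alone, camera adjusted p = 5.52e-16, adjusted p = 0.00150 with an estimated correlation), with H2-Ab1 at -1.97 ± 0.17. Of 15 immature T cell and recent thymic emigrant genes, 2 were higher and 5 lower in neonates and 8 did not pass (2 and 8 adjusted over the list alone, camera adjusted p = 0.0398, adjusted p = 0.586 with an estimated correlation). Of 23 monocyte and macrophage genes, 0 were higher and 8 lower in neonates and 15 did not pass (0 and 11 adjusted over the list alone, camera adjusted p = 8.34e-05, adjusted p = 0.290 with an estimated correlation). Of 11 NK cell and innate lymphoid cell genes, 0 were higher and 6 lower in neonates and 5 did not pass (1 and 6 adjusted over the list alone, camera adjusted p = 2.84e-05, adjusted p = 0.0290 with an estimated correlation). The count of 1964 was 3810 with limma voom, and it was 1111 and 1300 without neonatal E. coli library 1 or 2 and 1139 and 1108 without juvenile E. coli library 1 or 2. With covariates chosen after seeing the data it was 542 (immature T cell markers) and 728 (monocyte, macrophage and neutrophil markers), with the SE widened by the design by factors of 1.47 and 1.39.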

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

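In this part the tests of other cell types, gene length and other splits were chosen after the results were seen. Leaving out single libraries and the test of the difference of responses were planned. The response to E. coli differed between the ages in 774 genes, by the edgeR test of the difference itself. The log2 difference of responses (neonates minus juveniles) was 1.85 for Nkd2, 1.62 for Tspan9, 1.56 for Slc10a1, 1.54 for Amigo2, 1.39 for Gabrr2, 1.39 for Hcst and 1.35 for Rps14. It was 1.33 for Slc16a5, 1.20 for Gpr83, 1.04 for Igfbp4, 1.24 for Ccr7, 0.91 for Rpl8 and 0.54 for Tet1. It was -5.05 for Cxcl9, -3.53 for Kdr, -3.44 for Arpp21, -3.14 for Cav1, -3.14 for Scn7a, -3.09 for Phf11, -3.03 for Gpr116, -2.99 for Ifit3. It was -2.60 for Ifng, -2.07 for Gbp6, -2.01 for Il2ra, -1.86 for Cenpe, -1.86 for Ctla4, -1.81 for Mki67 and -1.72 for Prdm1. Smaller negative differences were -1.64 for Cxcr3, -1.52 for Foxp3, -1.28 for Anxa2, -1.18 for Parp14, -1.03 for Uhrf1, -0.89 for Maf and -0.87 for Rora. Camera called 19 lists, of which the Th1 list alone held with an estimated correlation. The median over the members of each was 0.20 for T cell identity, -0.48 for T cell activation, 0.67 for naive T cell and lymph node homing, -0.84 for Th1, -0.61 for Th2, -0.88 for Th17, -1.15 for regulatory T cell, -0.66 for cytotoxic effector and CD8 T cell. For the other called lists it was -0.83 for immature T cell and recent thymic emigrant, -0.84 for cell cycle, -1.45 for interferon response, -0.46 for NF-kB target, -0.42 for lung homing and tissue residency, -0.31 for glycolysis and hypoxia, 0.14 for oxidative phosphorylation, 0.67 for ribosomal protein, -0.62 for dendritic cell and MHC class II, -1.33 for lung epithelial and -2.58 for endothelial.

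Other splits of the same libraries were tested for each count. Of 100 drawn reassignments of the age labels within exposure (of 200 possible), 1, the real one, gave as many as 774 calls in the difference of responses, and the highest other gave 666. These reassignments also remove the age effect itself, and the 6 that kept the E. coli libraries of each age together gave 291 to 666 calls against at most 126 in the 93 that mixed them. So they follow the age contrast after E. coli and leave open how much of 774 is beyond chance. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 132 calls in neonates (highest other 13) and 2747 in juveniles (0). It gave 451 by age after PBS (0) and 1964 by age after E. coli (0).

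The first pattern weighed is the interferon response list, whose median difference of responses was -1.45 (median SE 0.287, 35 of 49 called, 2 members also in another list). Monocyte, macrophage and neutrophil markers as a covariate gave -1.50 (33 called), and endothelial and fibroblast markers, tried first, -1.55 (19 called). Immature T cell markers gave -1.34 (SE 0.391, 4 called). This argues against the number of these cells as the source, not their interferon response. Why calls were lost is untested. Dendritic cells are a candidate source inseparable from the groups, since 98.6% of their marker list's variance lies between them. That fit gave -1.37 (SE 0.571) and 0 calls with edgeR, with 491 at an unadjusted p under 0.05. Their list was written before the data were examined (1 of 15 members shared). Their most abundant transcripts were Ccr9 (122 ± 4.96 CPM in neonatal and 302 ± 74.1 in juvenile E. coli libraries) and Cd74 (98.9 ± 11.1 and 295 ± 33.3), of which Ccr9 is also in the immature T cell list, and a CD4 gate would keep dendritic cells that carry CD4. The limits of 95% between groups and 2 SE were set after seeing these values, and age stays open, untested.

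The second pattern is the ribosomal protein list, with a median log2 change of -0.61 after E. coli in juveniles (67 of 74 fell, 0 shared). Exon length, not mature transcript length, is argued against. The median of -0.61 over 73 members with a length lay under the lowest of 10000 lists matched on it and expression (-0.17). Juvenile PBS library 2 alone is argued against too, since without it the median was -0.48 (median SE 0.0947, 64 of 74 fell). Monocytes, macrophages and neutrophils hold ribosomal transcripts too and would lower T cell identity genes at least as far. That list's median was -0.26 (SD 0.191, 20 of 21 above -0.61). If T cells kept these genes level, untested, this argues against such cells as the whole source. A covariate of their markers, tried first, gave -0.073 (SE 0.262) and decided nothing with 89.8% of it between groups. Both lists were written before the data were examined (1 of 23 and 0 of 10 members shared). Their abundant transcripts in juvenile E. coli libraries were Ctsd (218 ± 16.6 CPM), Ccr2 (404 ± 34.1, also in the lung homing list) and Irg1 (24.5 ± 6.46), a CD4 gate would keep myeloid cells that carry CD4, and the response to E. coli itself stays open, untested.

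The third pattern is the spread of immature T cell genes between libraries of a group, such as Rag1 from 47.5 to 344 CPM in neonatal PBS libraries. Random loss of single transcripts is argued against, because the deviations of the 15 members from their group means had a mean pairwise correlation of 0.330 against at most 0.224 in 1000 lists matched on expression. Immature T cells carried through the sort cannot be told apart from other shared variation, since cell cycle (0.612, random at most 0.112) and ribosomal protein lists (0.459 and 0.120) exceeded random lists too, and the cell cycle sum was also highest in neonatal PBS library 1 (10070 CPM) and juvenile PBS library 2 (6817) of the PBS libraries of each age. The list was written before the data were examined (6 of 15 members shared). Its most abundant transcripts were Themis (625 ± 39.4 CPM in neonatal PBS) and Tox (263 ± 15.2). A CD4 gate would keep cells that carry both CD4 and CD8, and exclusion of CD8 is not given in the sources. Sex-linked sums varied too (108 to 362 CPM in neonatal and 159.5 to 388 in juvenile PBS), and no biological explanation was tested.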

How the results depend on the processing

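Most alternatives were planned, while the covariates and the fit without both PBS libraries high in Rag1 (neonatal 1 and juvenile 2) were chosen after the results were seen. Unless given here, each count of calls stayed within 1.5 times its main value, and the cause of each shift was not tested, except that fits with a library left out hold fewer libraries. Calls in neonates (132) were 235 with DESeq2, 312 with limma voom, 320 with only the groups compared, 55 (without PBS library 2) to 126 (without E. coli library 3) with a library left out. They were 56 without PBS library 1 and 62 without E. coli library 2, 75 with immature T cell markers as a covariate, and 0 with edgeR and monocyte, macrophage and neutrophil markers (447 at an unadjusted p under 0.05). Calls in juveniles (2747) were 4480 with limma voom, 1656 (without E. coli library 2) to 3204 (without PBS library 2) with a library left out. They were 1799 without E. coli library 1, and 718 and 16 with endothelial and fibroblast or with monocyte, macrophage and neutrophil markers. The difference of responses (774) gave 2300 with limma voom, 368 (without juvenile E. coli library 1, or 2) to 1553 (without juvenile PBS library 2) with a library left out. It gave 408 and 450 without neonatal PBS library 1 or 3, 372 and 433 without neonatal E. coli library 1 or 2, 504 without juvenile PBS library 1 and 1163 without juvenile E. coli library 3, and 15 and 57 with immature T cell or with endothelial and fibroblast markers. Age after PBS (451) gave 702 with DESeq2, 927 with limma voom, 280 with only the groups compared, 177 (without neonatal PBS library 1) to 671 (without juvenile PBS library 2) with a library left out. It gave 299 without neonatal PBS library 2 and 243 without juvenile PBS library 1, and 70 and 283 with endothelial and fibroblast or with monocyte, macrophage and neutrophil markers. Age after E. coli (1964) gave 3810 with limma voom, 1108 (without juvenile E. coli library 2) to 2063 (without juvenile E. coli library 3) with a library left out. It gave 1139 without juvenile E. coli library 1 and 1111 and 1300 without neonatal E. coli library 1 or 2, and 542 and 728 with immature T cell or with monocyte, macrophage and neutrophil markers. The 109 shared calls were 168 with DESeq2, 48 (without neonatal PBS library 2) to 109 (without juvenile PBS library 2) with a library left out. They were 49 without neonatal PBS library 1 and 54 without neonatal E. coli library 2, and 65 and 0 with immature T cell or with monocyte, macrophage and neutrophil markers.

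Lists called by camera (16, 24, 19, 17 and 18 in neonates, juveniles, the difference, age after PBS and age after E. coli) were 8, 9, 1, 1 and 9 with an estimated correlation and 14 to 20, 22 to 24, 18 to 22, 15 to 20 and 15 to 19 with a library left out. Fry called 11, 26, 13, 10 and 16 in the same order, and endothelial and fibroblast markers left 12 in the difference and 11 in age after PBS. Without both PBS libraries high in Rag1 the calls were 116, 3175, 1109, 365 and 2591, with 89 shared. With monocyte, macrophage and neutrophil markers the log2 change turned to -0.28 for Il1rn, -0.13 for Cxcl2, -0.25 for Fcgr2b and -0.11 for Emr1 in neonates. In juveniles it turned to -0.059 for Smarca4, -0.20 for H2-Eb1, -0.29 for Cd74 and -1.23 for Scgb1a1. The median of the monocyte and macrophage list turned to -0.42 and -0.40 in the responses, circular because that list makes the covariate. With endothelial and fibroblast markers Sparc turned to -0.18 in juveniles. Of these covariates 55.4% (immature T cell), 59.8% (endothelial and fibroblast) and 89.8% (monocyte, macrophage and neutrophil) of the variance lay between groups, and the last widened the errors by factors of 2.01 in neonates and 2.36 in juveniles. A further covariate, of dendritic cell and MHC class II markers, was tried and left out of the alternatives because 98.6% of it lay between groups. It gave 29 calls in neonates and 0 with edgeR in each other comparison, with 489, 491, 667 and 322 at an unadjusted p under 0.05 in juveniles, the difference, age after PBS and age after E. coli. Of the other gene values, alternatives chosen in advance left 11992 with the same call, while 353 gained and 649 lost a call, and with added ones these were 2603, 56 and 592. Of the other list values they were 1936, 60 and 139, and 605, 34 and 59. Replicate numbers did not pair the libraries (18 same-number correlations of -0.176 to 0.223, 2 over 0.1), and a replicate block gave 106, 2568, 645, 416 and 1780 calls and 90 shared. Depth limits genes under 0.374 to 0.494 CPM, such as Il17a in PBS libraries.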

Other observations

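The list tests in this part were planned before the results were seen. Of 26 glycolysis and hypoxia genes in juveniles, 12 rose, 1 fell and 13 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 0.000476, adjusted p = 0.276 with an estimated correlation). In the difference of responses 4 had a negative and 0 a positive difference and 22 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.00901, adjusted p = 0.526 with an estimated correlation). Of 43 oxidative phosphorylation genes in juveniles, 0 rose, 1 fell and 42 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.0220, adjusted p = 0.564 with an estimated correlation). In the difference 0 had a negative and 0 a positive difference and 43 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.0462, adjusted p = 0.670 with an estimated correlation). Of 25 polycomb and chromatin regulator genes in juveniles, 3 rose, 0 fell and 22 did not pass (3 and 0 adjusted over the list alone, camera adjusted p = 0.970, adjusted p = 0.977 with an estimated correlation). The heterochromatin protein Cbx5 (0.78 ± 0.11) and the polycomb methyltransferase Ezh2 (0.67 ± 0.14) rose.

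Of 6 gamma-delta and NKT cell genes in neonates, 0 rose, 0 fell and 6 did not pass (1 and 0 adjusted over the list alone, camera adjusted p = 0.0270, adjusted p = 0.117 with an estimated correlation). Of 11 B cell genes in neonates, 0 rose, 0 fell and 11 did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 0.0131, adjusted p = 0.385 with an estimated correlation). Of 5 mast cell, basophil and eosinophil genes in juveniles, 3 rose, 0 fell and 2 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.0393, adjusted p = 0.202 with an estimated correlation). Of 5 erythroid genes in juveniles, 1 rose, 1 fell and 3 did not pass (1 and 1 adjusted over the list alone, camera adjusted p = 0.525, adjusted p = 0.577 with an estimated correlation). Of 5 platelet and megakaryocyte genes, 1 rose, 1 fell and 3 did not pass (1 and 2 adjusted over the list alone, camera adjusted p = 0.315, adjusted p = 0.577 with an estimated correlation). Of 4 sex linked genes, 0 rose, 0 fell and 4 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.272, adjusted p = 0.633 with an estimated correlation).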
